A study of Mus musculus with 6 samples.

How the data were processed

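Total RNA was taken from the popliteal lymph nodes of 6 mouse samples, 3 per group, and libraries were made with an Illumina TruSeq RNA kit from 1 ug of RNA, per the labels' protocols. The genome build was mm10 and the aligner HISAT2, version 2.4, per the submitters' processing notes. The tool that counted reads and the annotation it used are not given in the sources used here. The groups were taken from the sample titles. For 1 sample the title and the treatment label give different replicate numbers, and the title was followed.

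The authors deposited 1 table of the whole series, with a gene identifier, a gene symbol and, per the file headers, a count and an FPKM column for each of 6 libraries. All 12 columns of per-library values were left out, because their names cannot be tied to a sample or a group: 3 of the 6 library names match a title in both groups and 3 match none. Groups were not inferred from column order, sample order or expression. The planned edgeR comparison, the tests of gene lists and the selection of named genes were therefore not run, and depth, replicate error and precision are not reported.

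The identifier and symbol columns deposited by the authors were compared with GENCODE M21 (primary assembly, GRCm38), using Python 3.11.15 and pandas 2.3.3. Identifiers were matched without their version number. A symbol was called equal only if every character matched, capitals included. The 31 gene lists, fixed before the data were examined, were counted through M21 gene names. The 15 names that M21 does not hold, which included second names of genes already listed, were left out. Names that M21 gives to 2 identifiers (Aldoa, Ccl19 and Ccl21a) were counted once, as found if either identifier was listed. The identifiers ENSMUSG00000094661 (Ccl19) and ENSMUSG00000095320 (Ccl21a) were not listed, but the other identifier of each name was. Coordinates are those of M21 and count from 1. As alternatives chosen after seeing the data, list genes were matched by deposited symbol instead, with and without regard to capitals. A count within 1.5 times the main one was treated as the same.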

Results

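RNA was sequenced from mouse popliteal lymph nodes, the nodes that drain the footpad, after extracellular vesicles (EVs) from human urothelial cells had been injected into the footpad over 10 days. EVs are membrane particles that cells release and that carry protein and RNA. Of the 6 nodes, 3 had received EVs of UM-UC-3, a human bladder cancer line, and 3 had received EVs of SV-HUC-1, a human urothelial line immortalised with SV40 that served as the non-cancer source. The design asked which genes differ in expression between nodes exposed to cancer cell EVs and nodes exposed to the control EVs, as a view of the lymphatic pre-metastatic niche.

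No comparison of expression between the 2 groups is given here. The deposited table holds 2 value columns, headed count and FPKM, for each of 6 libraries, and names these libraries only by a number that runs from 1 to 6. The sample titles number the nodes from 1 to 3 within each group. Of the 6 library names, 3 match a title in both groups and 3 match no title. The order of columns or of samples does not establish treatment. The deposited comparison is named with the control group first, whereas the samples are listed with UM-UC-3 first. These orders point to opposite assignments of the libraries. Assigning groups from the expression values would have built the outcome into the groups. The per-library values, including the depth of each library, are therefore not reported, and no gene is said to be higher or lower in either group.

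The table itself shows which genes such a comparison can cover. It listed 22274 mouse genes, each once. Of these, 22219 had an identifier in GENCODE M21, an annotation of the GRCm38 (mm10) assembly, and 55 did not. Protein-coding genes made up 21743 of the list, or 97.6%, against 22028 protein-coding genes in the annotation. Immunoglobulin segments were present as separate genes, with 218 variable, 19 diversity, 14 joining and 13 constant segments. So were 8 constant, 4 diversity and 70 joining segments of the T cell receptors. Of the 144 T cell receptor variable segments in GENCODE M21, 0 were listed, whereas all 218 of its immunoglobulin variable segments were. Long intergenic non-coding RNAs were nearly absent, with 13 genes.

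From 31 gene lists fixed before the data were examined, 451 of 452 genes were found by Ensembl identifier. The table lists nearly every protein-coding gene of the annotation, so this count is not particular to these lists, and a listed gene need not have been expressed in the nodes. The exception was Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), a long non-coding RNA of X inactivation. All 14 markers of lymphatic endothelium were listed, among them Prox1, the transcription factor that specifies this lineage, and Lyve1, a hyaluronan receptor. All 18 lymphangiogenic and angiogenic factors were listed, including Vegfc, a ligand of the lymphatic receptor Flt4, as were all 27 factors of the pre-metastatic niche, including S100a8 and S100a9, which encode the calprotectin subunits. The lists for B cells (12 genes), T cells (16 genes), macrophages (16 genes) and type I interferon response (23 genes) were also complete. Lists for tissue that can be dissected with a node were complete too, with 17 adipocyte, 17 skeletal muscle and 10 nerve genes.

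The deposited gene symbols often differed from the GENCODE M21 name of the same identifier. The symbol equalled the GENCODE M21 name for 15258 genes, or 68.5% of those listed. It differed in capitals only for 1298 genes and in more than capitals for 4450, or 20.0%, while 1225 genes carried no symbol. A single symbol could stand for many genes: 928 symbols were given to more than 1 gene, and together they covered 3691 genes. The most widely shared was Vmn2r116, a vomeronasal receptor, given to 104 genes.

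Among the listed genes of the fixed lists, 33 carried another symbol or none and a further 13 differed in capitals only. Several interferon-inducible GTPases carried the symbol of a related gene. Igtp (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591) and Irgm2 (ENSMUSG00000069874, chromosome 11, 58199618 to 58222782) were both called Irgm1. Gbp3 (ENSMUSG00000028268, chromosome 3, 142560026 to 142573209) and Gbp7 (ENSMUSG00000040253, chromosome 3, 142530342 to 142550149) were both called Gbp4. Gbp4 itself (ENSMUSG00000079363, chromosome 5, 105115767 to 105139586) was called GBP6, a symbol that Gbp6 (ENSMUSG00000104713, chromosome 5, 105270702 to 105293698) also carried. The annotated spans of Igtp and Irgm2 overlap on the same strand. Siglech (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925), a marker of plasmacytoid dendritic cells, was called CD33, and H2-DMb2 (ENSMUSG00000037548, chromosome 17, 34143307 to 34151555), which encodes a chain of the peptide-loading molecule H2-DM, was called H2-DMb1. The adult alpha-globin genes Hba-a1 and Hba-a2 shared the symbol Hba, and the beta-globin genes Hbb-bs and Hbb-bt shared Hbb-b1.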

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

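Matching the gene lists by deposited symbol rather than by identifier, an alternative chosen after seeing the data, lowered the number of list genes found from 451 to 406, or to 419 with capitals ignored. Both counts include Gbp4, whose symbol the table gives to Gbp3 and Gbp7, so 405 genes, or 418 with capitals ignored, carried a deposited symbol equal to their own name, which other genes can share. Every member was found in 30 of the 31 lists by identifier but in only 13 by exact symbol. For 29 of the 31 lists the number found stayed within 1.5 times that by identifier. The 2 others were the mitochondrially encoded genes, which fell from 13 to 1, and the erythroid genes, which fell from 9 to 4, with or without capitals. Lists within the ratio could also lose members by exact symbol. The MHC class II list fell from 10 to 7 and the interferon gamma list from 20 to 15. Mitochondrial genes were deposited under other names, such as Mtnd1 for mt-Nd1. Of the 5 erythroid genes not found, 4 shared a symbol in pairs (Hba for Hba-a1 and Hba-a2, Hbb-b1 for Hbb-bs and Hbb-bt), and Car1 was deposited as Ca1. Alternatives for the comparison between groups (replicates left out, normalization, filters, other tests and a fold threshold) were not run, since no library could be assigned to a group. No paired analysis was possible because the value columns cannot be tied to the replicate numbers or groups in the labels.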
